A study of Mus musculus with 11 samples.

How the data were processed

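Skin from 11 mice was profiled on Affymetrix whole-genome mouse arrays, 1 array per mouse. Vehicle was given to 3 mice, and 1 mg/kg of ABBV-075 to 8 mice, of which 4 gave skin at 6 h and 4 at 24 h after dosing. Per the labels' protocols, 200 ng of total RNA was amplified and biotin-labelled with a 3' IVT Plus kit. The kit primes from the 3' end of the transcript, so that a low 5' to 3' signal ratio of a control transcript accompanies shortened RNA. The labels give no collection time for vehicle skin.

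The authors deposited 1 table of 45101 probe set intensities per array, on a linear scale. The software, background method and scaling that made these intensities are not given in the sources used here. Between 12.9% and 16.6% of the intensities of an array lay below 0. The deposited intensities were not at a common level: the trimmed mean (2% left out at each end) ran from 82.8 to 244 between arrays. The number of arrays limits the precision of each value.

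The design fixed before the data were examined took log2(intensity + 16) of the deposited values, with no normalization between arrays, and listed quantile normalization as an alternative. That design was departed from. Because the arrays differed in brightness, the main values are quantile-normalized intensities, set to at least 0, then taken as log2(intensity + 16). The change was made after the intensities of the arrays and of a few genes had been inspected and before any gene was tested, but it was not written down at that point, and quantile, median, cyclic loess and no normalization were first run together. The choice decides how many genes are called at 6 h, so the count from the values as deposited stands beside each main count. Changes are differences on the log2(intensity + 16) scale, which understates the change of dim genes, and a value of 4.00 or near it is the floor.

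Of the probe sets, 34958 were annotated to 1 gene, 932 to several genes and 9211 were unnamed here. Symbols were updated through Entrez identifiers, which matched the reference gene table for 34754 probe sets. Each gene was represented by its brightest probe set over all arrays, and 13709 of 18194 genes were kept because that probe set lay above the 40th percentile of the array on at least 3 arrays. Some listed genes had no probe set annotated to them alone and were not analysed here, and 6 of the 20 polyadenylated histone genes were tested. Serpini1 and Nr1d1 were below the filter.

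Groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, in 1 fit over all 11 arrays with a mean per group and no covariate. The contrasts were 6 h minus vehicle, 24 h minus vehicle and 24 h minus 6 h. Adjusted p-values are Benjamini-Hochberg values over the genes kept, with a threshold of 0.05. Tests are two-sided. The 39 gene lists (20 pathway and 19 cell type lists) were fixed before the data were examined and tested with limma's camera at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with a correlation estimated for each list, and fry, were run beside it. Adjusted p-values over the list alone were computed too. The lists of reported BET inhibitor markers were drawn from general knowledge and may rest in part on these samples.

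Genes are named by a rule fixed before the data were examined: the 10 largest rises and falls among genes past the threshold whose groups do not overlap, or the 5 genes of smallest p where none passes; up to 4 members of smallest p per list; and 12 genes in every contrast. H2bc18 entered by that rule for 24 h minus 6 h and is followed at both times.

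The replicate numbers of the labels were checked for pairing through the correlation of deviations from group means over genes. For vehicle and 24 h the 3 same-numbered pairs had correlations of 0.25, 0.14 and 0.21, all over 0.1, which was the criterion for taking the numbers as pairs. Arrays of different numbers in these 2 groups correlated at 0.211, 0.169, 0.133, 0.116, 0.035, -0.273, -0.278, -0.344 and -0.350, the first being vehicle replicate 4 with 24 h replicate 2, above the 0.205 of vehicle replicate 4 with its own number. For 6 h and 24 h they were -0.06, -0.35 and 0.17, and for vehicle and 6 h, with 2 shared numbers, -0.12 and -0.07. No arrays of a group held the same values: at most 3 of the 45101 intensities were identical between 2 arrays.

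The procedure was tested on simulated data with the spread of the 13709 real genes. For a simulated 6 h against vehicle comparison, 37.0% of 100 genes planted with a log2 change of 1 and 81.0% of 100 planted with a change of 2 were called in the right direction, and 6 unchanged genes were called. Alternatives covered each array left out in turn, the normalization, filter, probe set choice, variance model, threshold, test, pseudocount, replicate block and set test. The actin 5' to 3' ratio as a covariate, and the fit without the 3 arrays whose ratio was under 0.3, were chosen after seeing the data.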

Results

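The series addressed which skin transcripts respond to ABBV-075 (mivebresib), an inhibitor of the BET bromodomain proteins that bind acetylated histones. Expression was measured in whole mouse skin from 3 vehicle mice, 4 mice at 6 h and 4 mice at 24 h after 1 mg/kg of the compound. Each mouse is 1 array, and values are log2 intensities given as mean ± SD, with changes as difference ± SE.

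Array brightness and the RNA control ratios differed between groups and between single arrays. The trimmed mean of the deposited intensities was 225 ± 19.4 (SD, n = 3) in vehicle, 140.5 ± 70.8 (SD, n = 4) at 6 h and 138.5 ± 30.4 (SD, n = 4) at 24 h. The 5' to 3' ratio of beta-actin, which falls with shorter RNA, was 0.547 ± 0.0564 in vehicle, 0.289 ± 0.156 at 6 h and 0.406 ± 0.145 at 24 h, with the lowest value, 0.0725, in 6 h replicate 5. The same ratio of Gapdh was 0.833 ± 0.117 in vehicle, 0.549 ± 0.297 at 6 h and 0.943 ± 0.112 at 24 h, so that at 24 h it lay above vehicle where the actin ratio lay below. Its low 6 h mean came mainly from replicate 5 (0.104), the other 3 arrays lying at 0.684 to 0.711. The bacterial spike controls averaged 4282 in vehicle, 4534 at 6 h and 4135 at 24 h. As deposited, the median gene differed from vehicle by -0.68 at 6 h and -0.62 at 24 h. After quantile normalization, used for all values here unless named otherwise, these differences were 0.0037 and -0.020.

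**Figure D1:**
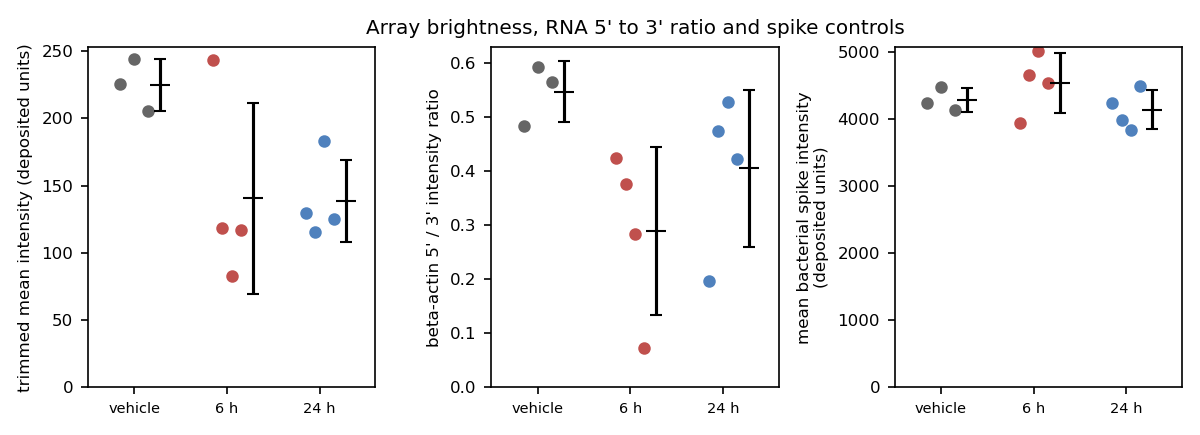
Trimmed mean intensity, beta-actin 5' to 3' ratio and mean bacterial spike intensity for each array (points) with group mean and SD (bars), for vehicle (n = 3), 6 h (n = 4) and 24 h (n = 4). Vehicle arrays had trimmed means of 205 to 244, while 6 h arrays ran from 82.8 to 244.

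At 6 h, Hexim1, which encodes an inhibitor of the elongation factor P-TEFb, averaged 9.90 ± 0.26 (n = 4) against 8.80 ± 0.12 (n = 3) in vehicle. The change was 1.10 ± 0.17, or 2.14-fold, and every 6 h array lay above every vehicle array. Of all genes tested, 18.6% did not overlap between these groups in either direction, where 5.7% were expected by chance. A second Hexim1 probe set gave a change of 1.39. In the values as deposited, where the median gene lay -0.68 from vehicle, Hexim1 differed by 0.30 ± 0.38. The histone gene H2bc18 was higher by 1.55 ± 0.25, again in every array. H2bc18 lies outside the fixed lists and is named here because of its small p between 24 h and 6 h. Neither gene passed over all genes, with limma adjusted p of 0.0638 for Hexim1 and 0.0667 for H2bc18. Hexim1 passed with array weights (adjusted p = 0.0015), with the mean of its probe sets (0.030), with no filter (0.039) and without 24 h replicate 4 (0.049), while its adjusted p was 0.55 as deposited. That was 1 of 11 fits leaving out 1 array, which ran up to 0.26. It was not called after median scaling, cyclic loess, a variance trend or the unequal-variance test. The fit with array weights called 2498 genes at 6 h, a count that 3 of 35 splits of the arrays reached. Adjusted over the list alone, Hexim1 was the 1 member called of 3 measured reported rising BET inhibitor markers (adjusted p = 1.2e-04), a list that may rest on these samples and is not independent evidence. Of the other reported markers, Zmynd8 differed by -0.44 ± 0.23 and Zcchc24 by -0.46 ± 0.29, both below vehicle and neither called. Myc differed by 0.16 ± 0.30, Brd2 by 0.25 ± 0.29 and Brd3 by 0.23 ± 0.20, all uncalled, and these 3 lay below vehicle in the values as deposited, Myc also after median scaling. Without 6 h replicate 1 Myc was 0.046 and Brd2 0.079, and without vehicle replicate 1 Brd3 was 0.14. At the other end, Myc was 0.35 and Brd2 0.45 without 6 h replicate 5, and Brd3 was 0.30 without 6 h replicate 3. Serpini1 was below the filter.

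**Figure D2:**
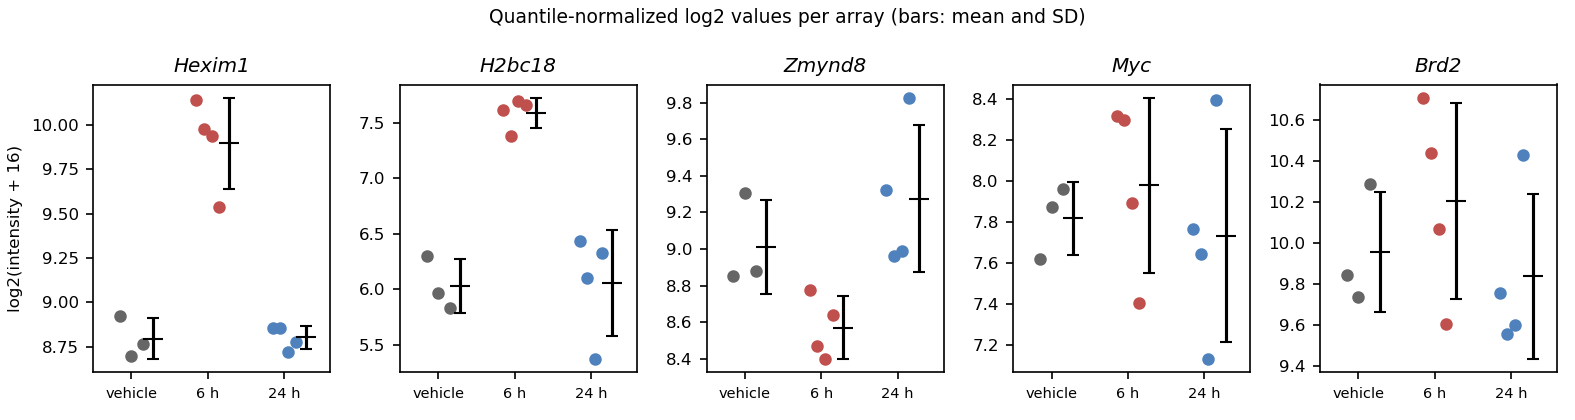
Quantile-normalized log2(intensity + 16) of Hexim1, H2bc18, Zmynd8, Myc and Brd2 for each array (points), with group mean and SD (bars). The 4 arrays at 6 h sit above all vehicle and 24 h arrays for Hexim1 and H2bc18, while Myc and Brd2 overlap between groups.

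The 5 genes of smallest p at 6 h were all lower and none passed. Ifitm3, an interferon-induced restriction factor, differed by -1.48 ± 0.20, from 12.78 in vehicle to 11.30. Thsd4 differed by -1.30, Gm11772 by -1.11, Kcnj14 by -1.40 and Hspa12b by -1.56, and each of the 5 had an adjusted p of 0.0638. Thsd4, Kcnj14 and Hspa12b lay near the floor at 6 h, at 4.19, 4.16 and 4.28.

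Interferon-stimulated genes were lower at 6 h in all 26 measured members, with a median change of -1.27 (camera adjusted p = 8.7e-12, and adjusted p = 0.88 with an estimated correlation). Oasl2 differed by -2.72, Ifit1 by -2.44, Dhx58 by -1.997 and Usp18 by -1.43, and 15 members were called lower adjusted over the list alone. Macrophage and dendritic cell markers were lower in 24 of 25 members (median -0.96; adjusted p = 0.88 with an estimated correlation), among them Fcgr1 at -2.54 and Cd68 at -1.53. Without vehicle replicate 1 the macrophage median was -0.63 and Cd68 -0.999. Adipocyte markers were lower in 15 of 16 (median -0.79; adjusted p = 0.88 with an estimated correlation), with Mest at -2.79 and the lipid droplet gene Plin4 at -0.98. Endothelial markers were lower in 18 of 20 (Ramp2 -1.30, Tie1 -1.02), extracellular matrix genes in 29 of 30 (Col6a2 -0.81, Mfap5 -1.53) and fibroblast markers in 17 of 17 (Clec3b -1.95), each with an adjusted p = 0.88 with an estimated correlation. The extracellular matrix call ended after median scaling (adjusted p = 0.11). Hair shaft genes were lower in 17 of 19 (median -0.95; adjusted p = 0.92 with an estimated correlation), with Psors1c2 at -1.06 and Krtap3-1 at -1.64. These rest on vehicle replicate 4, without which the median was -0.038, Psors1c2 -0.44 and Krtap3-1 -0.54. The hair shaft call also ended after median scaling (adjusted p = 0.19), with cyclic loess (0.16), as deposited (0.69), with a filter at the 60th percentile (0.15), with the mean of probe sets (0.14), without x_at and s_at probe sets (0.061) and with array weights (0.16). In the other direction, 6 of 6 polyadenylated histone genes were higher (median 0.64; adjusted p = 0.28 with an estimated correlation), with H1f2 at 0.95, H3c4 at 0.82, H2aw at 0.82 and H2aj at 0.36. P-TEFb, 7SK and BET factor genes were higher in 13 of 16 (adjusted p = 0.88 with an estimated correlation), with Ell2 at 0.55, Ccnt1 at 0.44 and Mepce at 0.43. Hexim1 belongs to this list too, so its call is not separate from the Hexim1 change. Ell2 was 0.33 without vehicle replicate 1 and Mepce 0.27 without 6 h replicate 1. Cholesterol biosynthesis genes were higher in 14 of 20 (Dhcr7 0.71, Hmgcs1 0.62), heat shock genes in 11 of 15 (Hspa1b 0.75, Hsp90aa1 0.56) and Myc target ribosome biogenesis genes in 19 of 26 (Npm1 0.46, Wdr43 0.61, and Rrp9 at -1.33), with adjusted p = 0.88, 0.88 and 0.92 with an estimated correlation. As deposited the medians of the P-TEFb, cholesterol, heat shock and ribosome biogenesis lists were -0.475, -0.49, -0.47 and -0.46 and none was called, and after median scaling the ribosome biogenesis call ended (adjusted p = 0.13). It also ended without x_at and s_at probe sets (0.068), and the cholesterol call ended with the mean of probe sets (0.11). The ribosome biogenesis median of 0.25 was 0.37 without 6 h replicate 5. H2aj, Ell2, Ccnt1, Mepce, Dhcr7, Hsp90aa1, Npm1 and Wdr43 lay below vehicle in the values as deposited, where the median gene differed by -0.68.

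These 12 lists, 5 higher and 7 lower, passed camera at its preset correlation. With an estimated correlation none did, the adjusted p being 0.28 for histone genes and 0.88 to 0.92 for the other 11 lists, and fry called 1 list, the histone genes (adjusted p = 0.0071). At the preset correlation 6 lists were called higher and 5 lower after median scaling, 2 higher and 6 lower as deposited, and 8 higher and 6 lower with array weights. Leaving out a single array ended 4 of the calls, with a highest adjusted p of 0.18 for cholesterol, 0.17 for heat shock and 0.25 for ribosome biogenesis genes, each without 6 h replicate 1, and 0.92 for hair shaft genes without vehicle replicate 4; the cholesterol call also ended without vehicle replicate 1 (0.13) or 6 h replicate 2 (0.070), and the heat shock call without the same arrays (0.14 and 0.079). The ribosome biogenesis call also ended without 6 h replicate 2 (0.085), 6 h replicate 3 (0.084) or vehicle replicate 4 (0.083), and the hair shaft call without 6 h replicates 1 (0.14), 2 (0.065) or 3 (0.12) or 24 h replicate 4 (0.055). The 6 h arrays with the lowest fibroblast and adipocyte list means, replicates 1 and 2, had basal keratinocyte list means 1.11 and 0.81 above vehicle. Cd180, a reported falling BET inhibitor marker, differed by -0.85, the B cell gene Ighm by -1.48 and the clock gene Cry1 by 0.90, none called over all genes. Adjusted over the list alone, Ighm (0.039) and Cry1 (0.0039) were called and Cd180 was not.

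**Figure D3:**
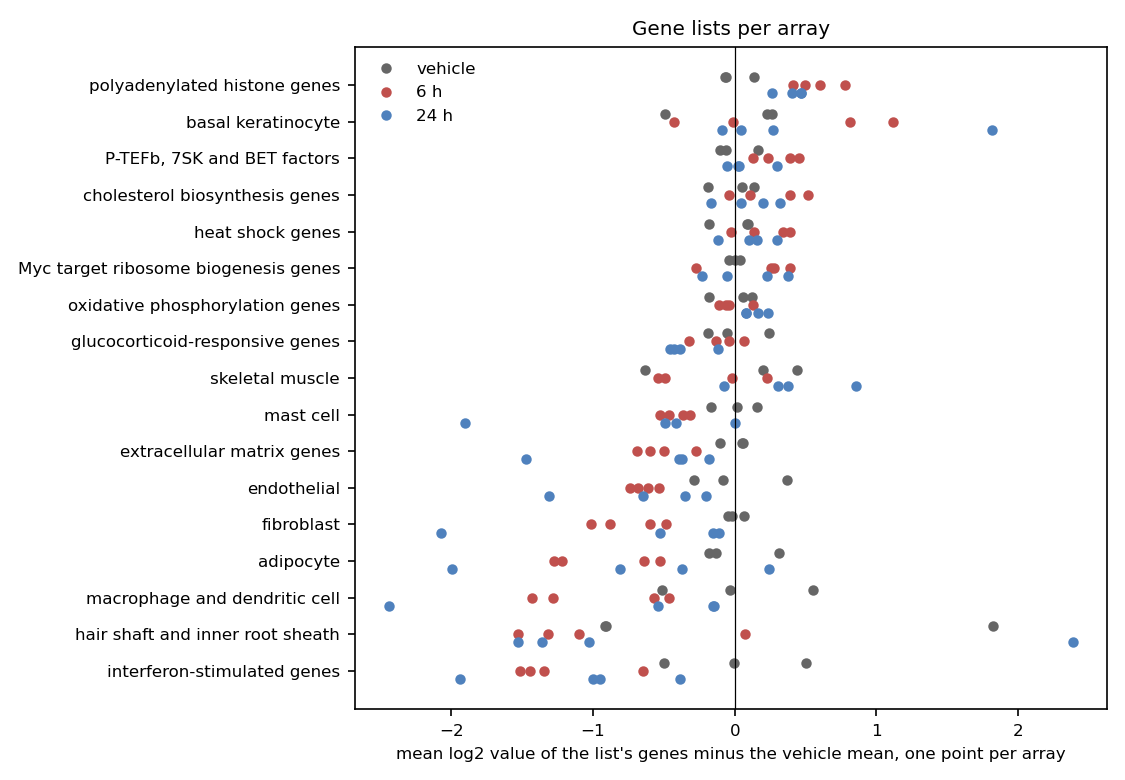
Mean log2 value of each list's genes relative to the vehicle mean, 1 point per array, for the lists past camera's preset test at 6 h or 24 h. The interferon-stimulated list lies at -1.51 to -0.65 in the 6 h arrays, and 24 h replicate 4 lies at -2.07 for fibroblast and 1.82 for basal keratinocyte genes.

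Counted over the 13709 genes, limma called 0 genes higher and 0 lower at 6 h, with 1099 higher and 1104 lower at an unadjusted p under 0.05, where 685 were expected, and an unequal-variance test of each gene called 0. In the values as deposited, the setting of the original design, 2 genes were called higher and 857 lower; with limma array weights 1057 were called higher and 1441 lower, vehicle replicate 3 then having a weight of 4.85 and vehicle replicate 1 one of 0.659. Without 24 h replicate 4 the fit called 22 genes at 6 h and without 6 h replicate 2 it called 2.

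At 24 h the clock genes moved in opposite directions. Arntl, the BMAL1 gene, was higher by 1.18 ± 0.19, from 7.28 ± 0.27 to 8.45 ± 0.16, and Npas2, a paralogue of Clock, differed by 1.08 ± 0.25. The genes of the opposite phase were lower, Dbp by -2.39 ± 0.45, Per2 by -1.71 ± 0.38 and Per1 by -1.61 ± 0.41, and every 24 h array lay beyond every vehicle array for these 5 genes. Of all genes tested, 11.1% did not overlap between these groups, where 5.7% were expected by chance. Adjusted over the list alone, 2 clock genes were called higher and 6 lower of 15; over all genes none was called. The list itself, with members moving both ways, did not pass camera at 24 h (adjusted p = 0.16). At 6 h Arntl differed from vehicle by 0.22 (-0.56 in the values as deposited), Per2 by -0.18 and Dbp by -0.013, all uncalled. Without 6 h replicate 3 Per2 was 0.029 and Dbp 0.20, and without vehicle replicate 4 Arntl was 0.10. Nr1d1 was below the filter. The labels do not say at what hour vehicle skin was taken.

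**Figure D4:**
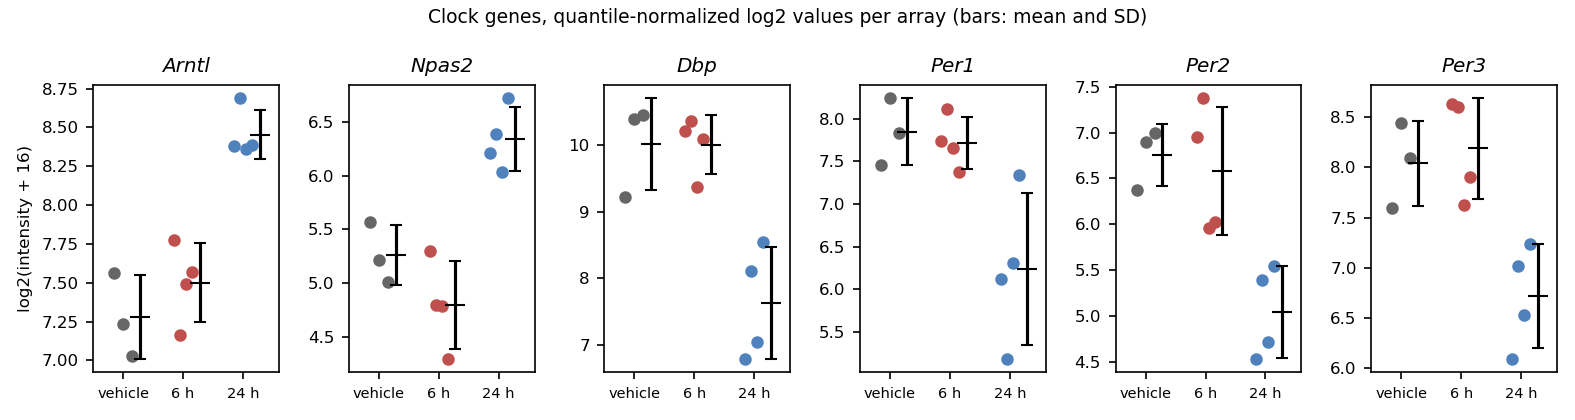
Quantile-normalized log2(intensity + 16) of 6 clock genes for each array (points), with group mean and SD (bars). Arntl and Npas2 are higher at 24 h, and Dbp, Per1, Per2 and Per3 lower, while vehicle and 6 h arrays overlap.

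Interferon-stimulated genes were again lower in 26 of 26 members at 24 h, with a median of -0.95 (camera adjusted p = 1.05e-12, and adjusted p = 0.64 with an estimated correlation). Oasl2 differed by -1.92, Dhx58 by -1.53 and Mx1 by -1.33, the 3 members called adjusted over the list alone. Without vehicle replicate 1 Oasl2 was -1.41 and Dhx58 -1.11, and without 24 h replicate 4 Mx1 was -1.05. At the other end, Oasl2 was -2.35 and Dhx58 -1.72 without vehicle replicate 3, and Mx1 was -1.64 without 24 h replicate 2. Extracellular matrix genes were lower in 26 of 30 (Col6a2 -1.05, Fn1 -1.45), macrophage and dendritic cell markers in 24 of 25 (Fcer1g -1.78, Fcgr1 -1.56), endothelial markers in 18 of 20 (Lyve1 -2.27, Ramp2 -1.07), fibroblast markers in 17 of 17 (Pdgfra -1.20), adipocyte markers in 15 of 16 (Mest -1.51) and mast cell markers in 8 of 9 (Mcpt4 -1.12, Kit -0.78), each with an adjusted p = 0.64 with an estimated correlation. Glucocorticoid-responsive genes were lower in 15 of 20 (adjusted p = 0.64 with an estimated correlation), with Klf15 at -1.22, and Per1 belongs to this list too. Skeletal muscle genes were higher in 21 of 22 (Tmod4 0.66, Myoz1 0.64), oxidative phosphorylation genes in 19 of 27 (Uqcrc2 0.42), basal keratinocyte markers in 11 of 11 (Trp63 0.63) and histone genes in 6 of 6 (H1f4 1.18, H2aj 0.37), with adjusted p = 0.64 with an estimated correlation, or 0.66 for basal keratinocyte markers. H1f4 lay near the floor in vehicle (4.544 to 4.615), and 24 h replicate 3 (4.293) lay below every vehicle array. Leaving out 1 array gave 0.81 to 1.69 for H1f4. H2aw overlapped between vehicle (8.689 to 8.891) and 24 h (8.741 to 8.938). Several of these gene values rest on 1 array: without 24 h replicate 4 Mcpt4 was -0.48, Pdgfra -0.68, Fcer1g -1.05, Fcgr1 -1.001 and Trp63 0.31, and without vehicle replicate 1 Tmod4 was 0.37, Myoz1 0.36 and Trp63 0.38. The oxidative phosphorylation median of 0.13 was -0.0097 after median scaling and -0.45 as deposited, and neither was called (adjusted p = 0.22 and 0.55). Myoz1, Tmod4, Uqcrc2, Trp63 and H2aj lay below vehicle in the values as deposited. Hexim1 differed from vehicle by 0.0062 ± 0.17 at 24 h and H2bc18 by 0.025 ± 0.25. Myc differed by -0.086, Brd2 by -0.12, Brd3 by 0.14, Zmynd8 by 0.26 and Zcchc24 by -0.34, all uncalled. Without 24 h replicate 4 Brd3 was 0.020, Zmynd8 0.080 and Zcchc24 -0.18, without 24 h replicate 1 Myc was 0.11, and without vehicle replicate 4 Brd2 was 0.047. The other ends were 0.23 for Brd3 without 24 h replicate 2, 0.41 for Zmynd8 without vehicle replicate 3 and -0.49 for Zcchc24 without 24 h replicate 3. For Myc and Brd2 they were -0.31 and -0.32 without 24 h replicate 4. Hexim1, H2bc18, Brd3 and Zmynd8 lay below vehicle at 24 h as deposited and after median scaling.

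These 12 lists, 4 higher and 8 lower, passed camera's preset test, and none passed with an estimated correlation (adjusted p = 0.64 to 0.66) or with fry. Array weights called 0 lists higher and 5 lower: interferon-stimulated, extracellular matrix and glucocorticoid-responsive genes passed, and the other 9 of the 12 did not (adjusted p = 0.064 to 0.69), among them all 4 higher lists. After median scaling 3 were called higher and 10 lower. Much of the 24 h shift in cell type lists came from 1 array: without 24 h replicate 4 the median was -0.22 in place of -0.64 for fibroblast, -0.25 in place of -0.84 for macrophage and dendritic cell, -0.30 in place of -0.64 for extracellular matrix, -0.38 in place of -0.64 for endothelial, -0.25 in place of -0.67 for adipocyte, -0.40 in place of -0.63 for mast cell and 0.073 in place of 0.55 for basal keratinocyte genes. Without vehicle replicate 1 the skeletal muscle median was 0.034 in place of 0.32, the oxidative phosphorylation median 0.070 in place of 0.13, and the endothelial, mast cell and basal keratinocyte medians -0.42, -0.41 and 0.26. Other arrays left out gave larger medians, for skeletal muscle 0.58 without vehicle replicate 4 and 0.53 without 24 h replicate 2, for oxidative phosphorylation 0.20 without 24 h replicate 3 and for adipocyte genes -1.04 without 24 h replicate 1. The interferon-stimulated median was -0.64 without 24 h replicate 4 in place of -0.95, and -1.305 without vehicle replicate 3. That list passed camera's preset test without each array in turn (highest adjusted p = 2.4e-08). Single arrays ended 7 of the 12 calls, with these highest values: adipocyte (adjusted p = 0.14), mast cell (0.098) and basal keratinocyte (0.59) without 24 h replicate 4, skeletal muscle (0.36) and oxidative phosphorylation (0.36) without vehicle replicate 1, histone genes (0.065) without vehicle replicate 4, and glucocorticoid-responsive genes (0.094) without 24 h replicate 1. The glucocorticoid call also ended without vehicle replicate 1 (0.083) or 24 h replicate 3 (0.065), the basal keratinocyte call without vehicle replicate 1 (0.35) and the oxidative phosphorylation call without 24 h replicate 1 (0.051) or 4 (0.072). A filter at the 60th percentile ended the histone (0.075) and glucocorticoid (0.082) calls, the mean of probe sets the histone call (0.073), and the actin covariate (0.091) or leaving out the 3 arrays of low actin ratio (0.082) the glucocorticoid call. With the replicate number as a block, immediate early genes (adjusted p = 0.044; Klf2 -0.93, Atf3 -0.89) and cholesterol genes (0.048) were called as well at the preset correlation. Without the block neither was called, with adjusted p = 0.65 and 0.68 with an estimated correlation and 0.50 and 0.66 with fry.

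The 5 genes of smallest p at 24 h, none passing, were Hspa12b at -1.81 (adjusted p = 0.0868), Mtarc1 at -1.60, Serpina1b at -3.01, Arntl and Ccdc138 at 0.87. Hspa12b lay at or near the floor in the 24 h arrays (4 to 4.084), which limits the size of its change. Cd180 differed by -0.87 and was the 1 reported falling marker called adjusted over the list alone, which is not independent evidence. Over all genes limma called 0 higher and 0 lower at 24 h, with 433 higher and 613 lower at an unadjusted p under 0.05, and an unequal-variance test of each gene called 0. In the values as deposited 0 were called higher and 6 lower; with array weights 25 were called higher and 34 lower, and without 6 h replicate 2 the fit called 1.

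Hexim1 differed by -1.09 ± 0.16 between 24 h and 6 h and H2bc18 by -1.53 ± 0.23, with every 24 h array below every 6 h array. Of all genes tested, 5.5% did not overlap between these groups, where 2.9% were expected by chance. Zmynd8 differed by 0.71 ± 0.21, called adjusted over the list of reported rising markers alone (adjusted p = 0.010), not independent evidence. Hexim1, H2bc18, Lzts3 (-1.73), Rem2 (-1.73) and A430046D13Rik (1.20) formed the 5 genes of smallest p, each with an adjusted p of 0.0672; Lzts3 and Rem2 lay near the floor at 24 h. Clock genes were lower at 24 h than at 6 h in 11 of 15 (adjusted p = 0.96 with an estimated correlation), Dbp by -2.37, Per2 by -1.54, Per3 by -1.47 and Per1 by -1.48, with Npas2 at 1.55 and Arntl at 0.95. Skin taken 6 h and 24 h after a dose can come from different hours of the day, which cannot be told apart from a response here. P-TEFb, 7SK and BET factor genes, a list that holds Hexim1, were lower in 12 of 16 (adjusted p = 0.96 with an estimated correlation), with Mepce at -0.66. Skeletal muscle genes were higher in 22 of 22 (Actn3 1.67, Myoz1 0.68), oxidative phosphorylation genes in 24 of 27 (Atp5g1 0.62, with Cox7c at -0.57) and hair shaft genes in 19 of 19 (Foxn1 0.48), each with an adjusted p = 0.96 with an estimated correlation. The oxidative phosphorylation median of 0.16 was -0.069 after median scaling, where the call ended (adjusted p = 0.77), as it did as deposited (0.42). Among histone genes H2aw, H3c4 and H1f2 differed by -0.79, -0.65 and -0.62 and were called adjusted over the list alone. The other 3 of the 6 members were higher, and the list was not called (camera adjusted p = 0.34). The epidermal gene Flg differed by -1.32, the replication gene Cdc6 by -0.80, Tsc22d3 by -0.82 and Bpgm by 0.53. Myc differed by -0.25, Brd2 by -0.37, Brd3 by -0.093, Zcchc24 by 0.12 (-0.016 after median scaling) and Oasl2 by 0.80, all uncalled. Without 6 h replicate 1 Brd2 was -0.20, without 24 h replicate 1 Myc was -0.045, without 24 h replicate 2 Brd3 was -0.00076 and without 24 h replicate 3 Zcchc24 was -0.029. At the other end, Brd2 was -0.57, Myc -0.47 and Brd3 -0.21 without 24 h replicate 4, and Zcchc24 was 0.33 without 6 h replicate 3.

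These 5 lists, 3 higher and 2 lower, passed camera's preset test between the times and none passed with an estimated correlation (adjusted p = 0.96) or fry. At the preset correlation 2 lists were called higher and 5 lower after median scaling, 2 higher and 4 lower as deposited, and 5 higher and 8 lower with array weights. The hair shaft median was -0.34 without 24 h replicate 2 and 0.88 without 24 h replicate 1, and of the 5 calls skeletal muscle alone passed without each array in turn: 1 list passed without 6 h replicate 1, 2 without 6 h replicate 2 or 24 h replicate 2, 3 without 24 h replicate 3, 10 without 6 h replicate 5 and 12 without 24 h replicate 4. The P-TEFb call ended without 6 h replicates 1 (adjusted p = 0.25) or 2 (0.17) or 24 h replicates 1 (0.14), 2 (0.14) or 3 (0.12), and the clock call without 6 h replicates 1 (0.25) or 2 (0.17) or 24 h replicates 2 (0.093) or 3 (0.058). The hair shaft call ended without 6 h replicates 1 (0.25), 2 (0.16) or 3 (0.14) or 24 h replicate 2 (0.78), and the oxidative phosphorylation call without 6 h replicate 1 (0.22) or 24 h replicate 4 (0.054). With no filter the P-TEFb (adjusted p = 0.10) and clock (0.053) calls ended, and with array weights the oxidative phosphorylation (0.24) and hair shaft (0.59) calls. The hair shaft call also ended with cyclic loess (0.071), a filter at the 60th percentile (0.27), the mean of probe sets (0.14), a pseudocount of 1 (0.091) and without x_at and s_at probe sets (0.061), and without the 3 arrays of low actin ratio its median was -0.078. Over all genes limma called 0 higher and 0 lower between 24 h and 6 h, with 516 higher and 755 lower at an unadjusted p under 0.05, and an unequal-variance test of each gene called 0. The values as deposited called 0, array weights 174 higher and 249 lower, and the fit without 6 h replicate 5 called 7, and 1 without 6 h replicate 2 or 24 h replicate 2.

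Changes at 6 h and 24 h correlated across genes with r = 0.71 (13709 genes, which are not independent replicates). Both use the same 3 vehicle arrays, and simulated unchanged groups against shared controls gave r = 0.57. The covariance was 0.134 against 0.0723 simulated, a difference of 0.0612. The simulation drew each gene independently, so it lacks variation shared by the genes of an array. A correlation as high was reached in 28 of 100 regroupings of the real arrays, so chance cannot be excluded. No gene was called at both times, which follows from the counts of 0. The 3 vehicle arrays were too few to split into separate controls. In the values as deposited 5 genes were called at both times, with array weights 36, and without 6 h replicate 2 there was 1.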

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

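The tests of collection time for the clock genes and of dermis content for the fibroblast genes were chosen only after their results were seen, as were the actin ratio covariate and the genes of the clock and dermis scores. Of 244 groups of 4 arrays tested for a single distant array, 16 had one, where chance gives about 12. The 16 include Hspa12b, Kcnj14 and Lzts3, whose other arrays were tied at the floor, where any difference counts as distant.

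Hexim1 and the list mean of the polyadenylated histone genes were higher in every 6 h array than in every vehicle array. Single histone genes were not all so. H2bc21 overlapped (6.902 to 7.362 in vehicle, 6.759 to 7.291 at 6 h). H1f4 in 6 h replicate 1 (4.383) lay below every vehicle array (4.544 to 4.615). The beta-actin 5' to 3' ratio went with 95 of 13709 genes. With it as a covariate the Hexim1 shift was 1.269 ± 0.124 (SE) and the histone shift 0.458 ± 0.0998 in place of 0.570. The ratio did not overlap between vehicle (0.484 to 0.593) and 6 h arrays (0.0725 to 0.425). The adjusted shifts therefore rest on a slope fitted within groups and cannot tell RNA quality apart from a response. With the dermis score (the mean of the fibroblast and adipocyte lists minus the basal keratinocyte list) as a covariate the Hexim1 shift was 1.053 ± 0.147. This argues against less dermis, by that score, as the whole cause. The content of other tissues, such as hair shaft or immune cells, was not tested. Scaling stays open: relative to the median gene of each array the smallest shift of 4 normalizations was 1.148, but that centring removes any factor per array, and as deposited the shift was 0.305 ± 0.376. A response to the compound stays open as a hypothesis too.

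Interferon-stimulated genes were lower at 6 h by a list mean of -1.239 ± 0.403. The shift was -1.728 with the actin ratio as covariate, which cannot exclude RNA quality because that ratio did not overlap between vehicle and 6 h arrays. It was -0.987 ± 0.444 at its smallest without 1 vehicle array, against a single vehicle array as the whole cause. Chance cannot be excluded: 2 of the 35 splits of the 7 arrays gave a shift as large, the highest other being 1.273. With the dermis score as covariate the shift was smaller, at -0.857 ± 0.306. Part of the shift therefore went with the score, so less dermis in the samples cannot be told apart from a response. The dermis score itself differed from vehicle by -1.20 ± 0.961 at 6 h, a difference close to its SE. For the fibroblast genes, the smooth muscle list lay above the fibroblast list by 0.562 ± 0.467 at 6 h, too imprecise to decide on less dermis.

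Clock genes shifted at 24 h, the mean of Dbp, Per1, Per2 and Per3 by -1.758 ± 0.373 beside 1.127 ± 0.186 for Arntl and Npas2. With the actin ratio as covariate the difference of these means was 2.796 ± 0.427. By itself that adjustment cannot decide, because among 24 h arrays only replicate 1 (0.529) lay within the vehicle range of the ratio (0.484 to 0.593). At 6 h the mean ratio was lower still (0.289 against 0.406 at 24 h), yet the difference of these means was -0.081 ± 0.398. This argues against RNA quality, by that ratio, as the whole cause. The opposite movement is what another hour of collection could give, and this cannot be told apart from a response because the labels give no hour for vehicle skin.

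Single arrays stood apart from the other 3 of their group in these values. For 24 h replicate 3, Arntl was 8.692 and Hspa12b 4.084. For 24 h replicate 4, Ell2 was 9.227, Lzts3 4.258, Mcpt4 5.162 and Pdgfra 8.122, and list means relative to vehicle were -0.0415 for clock genes and -1.474 for extracellular matrix genes. For 24 h replicate 2 the hair shaft list mean was 2.385. For 6 h replicate 3, H3c4 was 5.246, Kcnj14 4.627 and the hypoxia list mean -0.1233. For 6 h replicate 5, Ifit1 was 7.081, Mx1 6.165, Psors1c2 6.353 and the Gapdh 5' to 3' ratio 0.1037. For Hspa12b, Kcnj14 and Lzts3 the other 3 arrays were at the floor.

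The effects at 24 h and 6 h differed by camera's preset test for 5 lists, with median differences of 0.457 for skeletal muscle, 0.165 for oxidative phosphorylation, -0.799 for clock, -0.206 for P-TEFb, 7SK and BET factor and 0.556 for hair shaft genes. None of the 5 passed with an estimated correlation (adjusted p = 0.96 for each) or with fry. The 18S ribosomal RNA 5' control probe set, outside the gene tests, averaged 6300 ± 3951 at 24 h, 655 ± 591 at 6 h and 2710 ± 1500 in vehicle.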

How the results depend on the processing

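The actin ratio covariate and the fit without the 3 arrays of low actin ratio were chosen after the data were seen; the values as deposited are the setting of the original design. No gene was called in any contrast after median scaling, cyclic loess, a filter at the 60th percentile, a variance trend, other pseudocounts or the unequal-variance test of each gene. Where no cause is given below, the cause was not tested.

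Genes called at 6 h numbered 859 as deposited, where the median gene shifted by -0.68, 2498 with array weights, 18 with no filter, 7 with the mean of probe sets, and 1 each with a replicate block, only the 2 groups compared or all probe sets. At 24 h they numbered 6 as deposited, 59 with array weights, 2 with only the 2 groups and 1 with no filter. Between 24 h and 6 h they numbered 423 with array weights, 3 with the actin covariate, 2 with the mean of probe sets, and 1 each without x_at and s_at probe sets or with all probe sets. At both times they numbered 5 as deposited, 36 with array weights and 1 with no filter. Leaving out 1 array gave 0 to 22 genes at 6 h, 0 to 1 at 24 h, 0 to 7 between the times and 0 to 1 at both.

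With an estimated correlation 0 lists were called in each contrast (smallest adjusted p 0.28, 0.64 and 0.96), and with fry 1, 0 and 0. Lists at 24 h numbered 5 with array weights. Between 24 h and 6 h they numbered 15 with a replicate block, where oxidative phosphorylation genes were not called (adjusted p = 0.053), 13 with array weights, 3 with no filter, 10 with the actin covariate and 14 without the 3 arrays. Leaving out 1 array gave 8 to 13, 10 to 17 and 1 to 12 lists. The hair shaft list between the times was -0.07762 without the 3 arrays and -0.3366, without 24 h replicate 2, to 0.8783 leaving out 1 array. The correlation of 6 h and 24 h changes was 0.7625 as deposited, 0.5167 with array weights, 0.7604 with the actin covariate and 0.6079 to 0.7617 leaving out 1 array.

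As deposited, these gene values turned below 0. At 6 h Myc was -0.6606, Brd2 -0.5292, Brd3 -0.5955, Arntl -0.5582, H2aj -0.3775, Ell2 -0.1896, Ccnt1 -0.3385, Mepce -0.3849, Dhcr7 -0.07911, Hsp90aa1 -0.06964, Npm1 -0.04217 and Wdr43 -0.1999. At 24 h Hexim1 was -0.7374, H2bc18 -0.3988, Zmynd8 -0.4963, Brd3 -0.6007, Myoz1 -0.07064, Tmod4 -0.0525, Uqcrc2 -0.2426, Trp63 -0.07136 and H2aj -0.3716. After median scaling Myc was -0.03674 at 6 h, Hexim1 -0.3091, H2bc18 -0.04755, Zmynd8 -0.06543 and Brd3 -0.1804 at 24 h, and Zcchc24 -0.01601 between the times. After cyclic loess Hexim1 was -0.009521 at 24 h.

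With a replicate block Dbp was 0.321 and Per2 0.1321 at 6 h and H2bc18 -0.006515 at 24 h. With the mean of probe sets H2aj was -0.04683 at 6 h and Brd3 -0.09476 at 24 h. With array weights Per2 was 0.155 at 6 h, and H2bc18 -0.1825 and Zmynd8 -0.09483 at 24 h. With the actin covariate Dbp was 0.2335 and Per2 0.3115 at 6 h, Brd2 0.029, Myc 0.03367 and H2bc18 -0.06026 at 24 h, and Zcchc24 -0.005129 between the times. Without the 3 arrays Dbp was 0.261 and Per2 0.4155 at 6 h, and Hexim1 -0.01174 and H2bc18 -0.1072 at 24 h.

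Leaving out 1 array gave, at 6 h, -0.4094 to 0.198 for Dbp and -0.4494 to 0.0291 for Per2. At 24 h it gave -0.04274 to 0.06984 for Hexim1, -0.1017 to 0.2555 for H2bc18, -0.3096 to 0.1148 for Myc and -0.3191 to 0.04653 for Brd2. Between the times it gave -0.02867 to 0.3323 for Zcchc24. None of these genes was called at that time in the values used for the report. Between 12.9% and 16.6% of intensities lay below 0, which limits what dim genes can show.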

Other observations

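The regroupings with array weights and in the values as deposited were chosen after both settings were seen to move the count at 6 h. The following lists were not called in any contrast of the main fit, though some were with a replicate block. Sebocyte genes had a median change of 0.33 at 6 h and 0.059 at 24 h, hair follicle bulge and germ genes 0.15 and 0.17, melanocyte genes 0.17 and 0.21, p53 target genes 0.095 and 0.056, and neutrophil genes 0.10 and 0.066. Inflammatory cytokine and NF-kB genes had medians of -0.26 and -0.33, autophagy and lysosome genes -0.14 and -0.13, unfolded protein genes -0.071 and -0.15, Langerhans cell genes -0.056 and -0.20, fatty acid synthesis genes -0.013 and -0.15, T cell genes -0.17 and -0.070, Schwann cell genes -0.073 and -0.10, and smooth muscle genes -0.092 and -0.007. Proliferation genes had medians of 0.044 and -0.061, B cell genes 0.066 and -0.22, erythroid genes -0.065 and 0.14, hypoxia genes -0.071 and 0.053, suprabasal keratinocyte genes 0.20 and -0.034, immediate early genes -0.091 and -0.15, and reported falling BET inhibitor markers -0.20 and -0.18.

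The median, mean and camera direction of some lists differed in sign. Reported rising BET inhibitor markers had a median of -0.44 and a mean of 0.067 at 6 h, where camera gave up, since Hexim1 was the 1 of 3 members above vehicle. T cell genes had a median and mean below 0 at 6 h and 24 h with camera up, and B cell genes a median of 0.066 and a mean of -0.17 at 6 h with camera down. Of 5200 probe sets outside the gene tests, being unnamed here or shared between genes, limma called 0 at 6 h, 0 at 24 h and 3 between the times, with smallest adjusted p of 0.0525, 0.147 and 0.0162.

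Regrouping the arrays tested whether chance gives results as large. For called genes it could not: each real count is 0, which 35 of 35 splits reach by construction (highest other 1 at 6 h, 2 at 24 h and 15 between the times). At 6 h the 2203 genes at an unadjusted p under 0.05 were reached by 1 of 35 splits, the real one (highest other 1892). That is the smallest share 35 splits can give and is not adjusted for the other counts tested. It argues against chance without excluding it. Chance cannot be excluded for the 12 lists (10 splits, highest other 18), the 2498 genes with array weights (3 splits, highest other 4667) or the 859 genes as deposited (2 splits, highest other 9696). What gave the last 2 highest counts was not tested. At 24 h chance cannot be excluded for the 1046 at an unadjusted p under 0.05 (4 splits, highest other 1306) or the 12 lists (19 splits, highest other 17). There were 8 splits that part the 3 same-numbered pairs of vehicle and 24 h arrays as the real one does. Of these, 1 reached the count at an unadjusted p under 0.05 (highest other 748) and 4 the count of lists (highest other 16). With 8 splits, 1 of 8 is the smallest share possible, so they cannot exclude chance. Between 24 h and 6 h chance cannot be excluded for the 1271 at an unadjusted p under 0.05 (7 splits, highest other 3493) or the 5 lists (30 splits, highest other 17). What gave the count of 3493 was not tested. The correlation of 0.71 between 6 h and 24 h changes was reached in 28 of 100 regroupings, the highest other being 0.838.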
